A study of Drosophila melanogaster with 2 samples.

How the data were processed

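The series holds ChIP-seq of GFP-tagged Bsh from whole embryos, with 2 biological replicates of 1 group. Per the labels, chromatin was sheared by sonication, with a size range of 200 to 800, and coordinates are on assembly dm6. The age was taken from the source name in the labels, because their age field holds a value that cannot be an age of embryos, and the antibody from their description, because their antibody field names bsh itself. Per the deposited text files, peaks were called on each replicate and on the pooled replicates, in each case with the same control file, and the IDR-thresholded set was derived from these 3 lists. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. The control sample was not analysed here.

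All 4 lists are in narrowPeak format. The signal value of each peak is a score that the authors' peak caller gave, in a scale that differs between lists, so replicates were compared by peak ranks and by the correlation of log2 values, and no ratio was taken between lists. The deposited lists also give the −log10 of a q-value, which sits at its maximum of 4.33 for every IDR peak and was not used to rank. The position of the summit within the peak is another value given by the authors, in bp from the peak start, and all results on location, genes and motifs use this summit. Each of the replicate and pooled lists holds exactly 30000 peaks, so their length is a set limit and not a count of bound sites. The 7927 IDR peaks are identical to the 7927 peaks of highest signal value in the pooled list, so the alternative that replaces the former by the latter changes no peak. No peak was identical in both replicate lists. The depth per sample is unknown, since no reads or counts were used. Intervals on shares of peaks are exact binomial and treat summits as independent; they cover counting error only and not the spread between embryos or replicates.

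The genome and gene annotation were those of *Drosophila melanogaster* genome release 6, with Ensembl release 115 gene models. All peaks and annotated genes lay within the chromosome lengths of that genome. Analyses covered the arms 2L, 2R, 3L and 3R and the chromosomes 4, X and Y, and the gene lists left out Y. They were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

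Replicates were compared at equal numbers of peaks, taking the strongest 1000, 5000, 7927 or 20000 peaks or the whole lists, with an overlap of at least 1 bp. The reference was 1000 random circular shifts of the second list within each chromosome. Each IDR summit was put in the class that came first among promoter (within 500 bp of any annotated TSS), 5′ UTR, 3′ UTR, coding exon, other exon, intron and intergenic. The share of summits in each of the 7 classes was compared with the share of bases, weighted by peaks per chromosome, by an exact two-sided binomial test. Arms were tested in the same way against their lengths.

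The 20 gene lists, the 14 motifs, the rule for named genes and the tests of replicates, locations, arms, lists and motifs were fixed before the data were examined. A gene was counted where at least 1 IDR summit lay in its span extended by 2 kb either side. The number of such genes in a list was compared with 100000 random lists of protein-coding genes matched on window length in 20 bins, with a two-sided permutation p. The random lists drew genes independently of their position. Neighbouring members of the Notch pathway and chemosensory receptor lists have overlapping windows, so the p-values of such lists may be too small. Of the symbols fixed, 4 were not matched to a gene of the annotation and were left out, 2 more were synonyms of genes already in the same list, and some genes belong to more than 1 list. Motifs were searched on both strands within 50 bp of the summit, and in a window of the same width centred 500 bp to 1 side, chosen at random with a fixed seed. Discordant peaks, with the motif in only 1 of the windows, were tested by the exact two-sided McNemar test, and the odds are the ratio of discordant peaks. Tests of location classes, arms, gene lists, motifs, sequences of fixed length and gene types were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05; the replicate overlaps were not adjusted. The genes named are bsh, those with the TSS nearest to the 20 strongest IDR peaks, the 10 with the most summits, and in each list the 4 with the strongest peak in the window and up to 3 without a summit in alphabetical order. One gene that this rule names is not reported here. Where a gene's strongest peak is given, the number in brackets is its signal value in the pooled replicates. Such a peak lies in the gene's window but can be nearer to the TSS of another gene, which is not stated in every case.

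Alternatives fixed beforehand were the 3963 or 1000 strongest IDR peaks, the strongest peaks of the pooled list, peaks of replicate 1 that overlap replicate 2, each replicate alone, merged peaks, promoters of 250 or 1000 bp, and gene windows of 1 kb around a TSS, nearest TSS, or 10 kb either side. Further ones were random lists matched also on chromosome, autosome arms only, motif windows of 25 or 100 bp, flanks 1000 bp away, positions matched on GC content and TSS class, and stricter definitions of overlap. Added after the data were seen were random lists matched also on the number of TSS positions, summits within 100 bp of an own TSS, locations against random positions matched on chromosome and GC content, and arm lengths without Y. For summits within 100 bp of an own TSS, the share of list genes was divided by that of all other protein-coding genes. That ratio was not matched on length and was tested by the exact Fisher test.

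The replicate overlap, the location classes, the gene lists and the fixed motifs against flanks were tested on simulated data with known answers. The tests of arms, matched positions, summits near an own TSS, divergent promoters, gene types and longer sequences were not simulated. With 50% of peaks planted as shared, an overlap of 50.8% was found, against 1.78% after shifting. Uniform positions gave 6 calls in 100 sets of tests of the 7 location classes, and a planted promoter share of 35.2% was found as 35.4%. Random lists of 30 long genes were called, at an unadjusted p under 0.05, in 1.5% of draws, and lists with 95% of genes planted as bound in 99.5%. Smaller lists and weaker differences were not simulated, so these shares do not give the power for the lists that did not pass. None of the 14 motifs was called at uniform random positions against their flanks, and planting TAATTA in 1 of 20 windows gave odds of 1.87. Such positions lack the difference in GC content between summits and flanks, so calls due to base composition were not tested by this simulation.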

Results

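Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the DNA bound by Bsh in whole *Drosophila melanogaster* embryos aged 10 to 12 h. The gene bsh (brain-specific homeobox) encodes a homeodomain transcription factor known for its role in specifying neurons of the optic lobe. The embryos came from a transgenic line in which the protein carries green fluorescent protein (GFP) at its C-terminal end, and an antibody against GFP was used for the precipitation. The data comprise 2 biological replicates of this 1 group, so no comparison between conditions could be made. The comparisons made were between the replicates, and between the peaks and random placement on the genome, random gene lists or neighbouring sequence. The number of reads behind each replicate is unknown, because the peak lists carry no read counts, and no control sample was analysed here.

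The replicates placed their strong peaks at largely the same positions. Each replicate list and the list from the pooled replicates held 30000 peaks. The authors' set from an analysis of the irreproducible discovery rate (IDR), a measure of how reproducibly peaks rank between replicates, held 7927 peaks. It was identical to the 7927 peaks of highest signal value in the pooled list, so single peaks in it need not rank alike in both replicates. These IDR peaks formed 7777 separate loci, covered 2271163 bp or 1.65% of the chromosome arms, and had a median width of 283 bp. Their signal value, a score given by the authors' peak caller, ranged from 151.5 to 8178 with a median of 312. Of the 7927 strongest peaks of replicate 1, 6837 (86.2%) overlapped 1 of the 7927 strongest of replicate 2 by at least 1 bp, and 85.8% did in the reverse direction. In 1000 circular shifts of the second list along its chromosomes the overlap averaged 3.29% and never exceeded 4.39% (permutation p = 1.0e-03, the smallest possible). The overlap was 90.5% for the 1000 strongest peaks and 74.2% for the whole lists, for which shifted lists averaged 13.9%. Of the 7927 IDR peaks, 7869 (99.3%) had a peak in both replicates, 30 lacked one in replicate 1 and 28 lacked one in replicate 2. Across these 7869 peaks, which are not independent replicates, the log2 signal values of both replicates had a Pearson r of 0.936 and a Spearman rho of 0.90. IDR peaks are the strongest of the pooled replicates, so these shares and correlations describe that selected set only. Both replicate lists were made with the same control file, so part of their overlap can come from that file.

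Promoters held 2863 of the 7927 IDR summits, 36.1% (exact binomial 95% interval 35.1 to 37.2), where 13.5% of the bases lay within 500 bp of an annotated transcription start site (TSS), a 2.67-fold excess. Coding exons were almost empty of summits: 14 summits, 0.177% (0.0966 to 0.296), lay in the 13.1% of bases annotated as coding and outside promoters. Both p-values of the exact two-sided binomial tests were too small to be represented in double precision. Introns held the most summits, 3353 or 42.3%, close to their 39.4% share of the bases (1.07-fold, adjusted exact p = 3.2e-07). Promoters held more than introns among the 1000 strongest peaks (477 against 369) and when drawn to 1000 bp (3684 against 2838). Intergenic sequence held 1478 summits, 18.6% against 27.3% (0.683-fold, adjusted exact p = 5.7e-72), and 3′ UTRs held 84, 1.06% against 5.06% (0.209-fold, adjusted exact p = 6.9e-85). Exons of non-coding transcripts and other unclassified exons held 91 summits (1.41-fold, adjusted exact p = 0.00201), and 5′ UTRs outside promoters held 44 (0.711-fold, adjusted exact p = 0.0213). The strongest quintile of peaks by signal value had the highest promoter share, 44.3% (41.9 to 46.8), and the other quintiles lay between 33.1% and 35.7%. The fold turned for introns (0.936) and the calls for 5′ UTRs (0.385) and other exons (1.47) were lost among the 1000 strongest peaks, as they were for introns (0.990) and other exons (1.23) with promoters drawn to 1000 bp, and for 5′ UTRs without replicate 1 (0.792). Against random positions of matched GC content, a reference chosen after the data were seen, coding exons held 0.0534 and 3′ UTRs 0.142 of the matched share, introns 0.940, past the threshold in the opposite direction, and the calls for 5′ UTRs (1.1) and other exons (1.30) were lost.

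**Figure D1:**
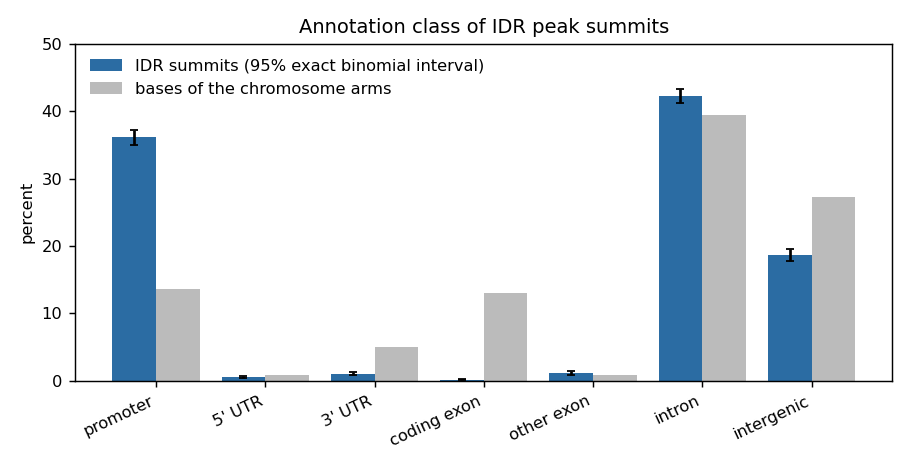
Percent of the 7927 IDR peak summits in each annotation class (blue bars, with exact binomial 95% intervals) beside the percent of bases of the chromosome arms in that class, weighted by peaks per arm (grey bars). Promoters held 36.1% of summits on 13.5% of the bases, and coding exons 0.177% on 13.1%.

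Each of the 20 strongest IDR peaks was among the 22 strongest of both replicates, and 15 of them had their summit in a promoter, 3 in an intron and 2 in intergenic sequence. The strongest peak of all lay on 3L at 19590398 to 19590846 (assembly dm6), with its summit 91 bp from the TSS of CG14100 and a signal value of 8178. The next lay in promoters of px (plexus, a gene of wing vein patterning; 2R, 22514060 to 22514531, signal value 7937) and Ugalt (a UDP-galactose transporter; X, 2703652 to 2704118, 7101). Peaks at the promoters of ph-p (polyhomeotic proximal, a Polycomb group gene; 6649), mRpL41 (a mitochondrial ribosomal protein; 6135), Chro (Chromator, a protein of interbands and the mitotic spindle; 5840) and PNPase (a mitochondrial RNA-degrading enzyme; 5111) followed. Promoter peaks also lay at Art3, CG1888, CG18549, CG5611, Fkbp14, RluA-1, Tcs5 and CenG1A. The intronic peaks had as their nearest protein-coding TSS those of CG11050, cbt and Lk6, and the intergenic peaks those of CG13323, at 11911 bp, and CG31668, at 3750 bp.

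Counted by summits in the gene span with 2 kb either side, kirre led with 44 summits in 394149 bp. It encodes an adhesion protein of muscle founder cells, and its strongest peak was intronic (X, 3097008 to 3097414, signal value 2260). CG1677 held 21 summits, and 20 each lay in fz, the Wnt and planar polarity receptor frizzled, in hth, the homeodomain Hox cofactor homothorax, and in sick. CG43658 had 19, Hr4 and Ptp61F had 18 each, and Ten-a, a teneurin of synaptic partner matching, and ush, a GATA cofactor, had 17 each. These genes span between 64341 and 394149 bp and fell in the longest of the 20 length bins, where 67.2% of genes had at least 1 summit. That bin also holds shorter genes, such as pdm2 with 29142 bp. The share is no reference for the number of summits per gene. In all, 5834 of 13945 protein-coding genes (41.8%) had a summit in this window, and 1163 summits lay in no gene's window.

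The tagged gene itself had no IDR summit inside its transcribed span. bsh (FBgn0000529) lies on the minus strand of 2L at 19765776 to 19769067, and 2 summits fell in its window, both beyond its 3′ end and both within the promoter of the neighbouring gene fbp (fructose-1,6-bisphosphatase). The stronger, at 19764120 to 19764397, had a signal value of 352 and lay 170 bp from the fbp TSS, and the weaker, at 19764414 to 19764650, had 265 and lay 376 bp from it. The weaker peak ranked 2824 in replicate 1 and 14866 in replicate 2. The strongest peak within 20 kb of the gene, at 19758535 to 19758893 with a signal value of 1474, lay 102 bp from the TSS of CG10628 and ranked 373 and 450 in the replicates. Of genes as long as bsh, 44.0% had a summit in their window.

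**Figure D2:**
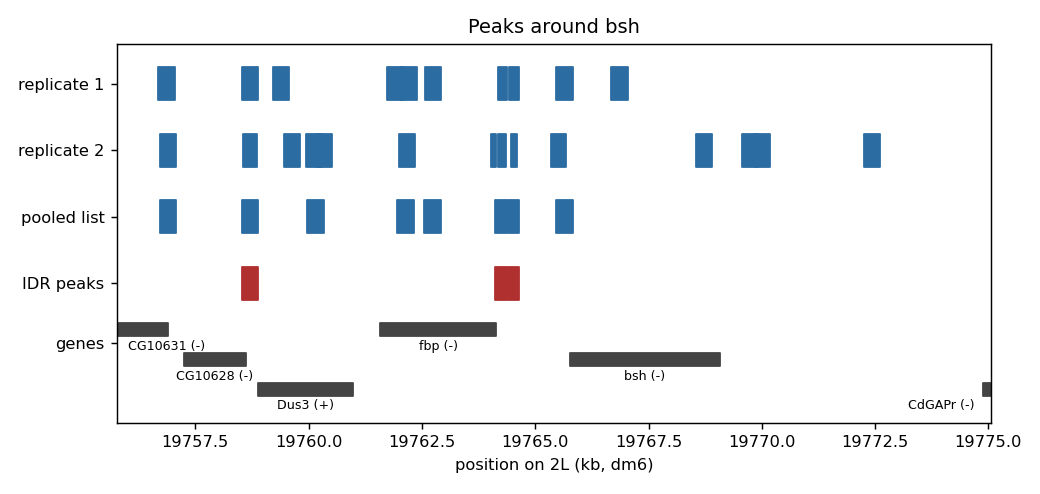
Peaks around bsh on chromosome 2L (x axis in kb, dm6) in the lists of replicate 1, replicate 2 and the pooled replicates (blue) and in the IDR set (red), above the protein-coding genes with their strands (dark grey). The IDR peaks lie at the promoters of CG10628 and fbp, and none lies within bsh.

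Of the 20 gene lists fixed before the data were examined, ribosomal protein genes held summits far more often than length-matched genes. A summit lay in the window of 79 of the 92 genes (85.9%), against a mean of 30.4 and a 95% range of 22 to 39 in 100000 random lists, a ratio of 2.60 (two-sided permutation p = 2.0e-05, the smallest possible, adjusted permutation p = 1.3e-04). Of these 79 genes, 72 had a summit within 500 bp of an own TSS, and 69 were the gene with the nearest TSS for at least 1 summit. Among the strongest peaks in their windows were those of RpL3 (3017), RpL31 (1554) and RpS3 (1248). These 3 had another gene's TSS nearest to the summit, that of CG17726, CG1827 and Sec13. RpL10Aa, RpL21 and RpL22-like were among the 13 genes with no summit. Among the 1000 strongest IDR peaks, the ratio was 1.64 and did not pass the test. It was 1.44 with 10 kb either side of the gene. Within 100 bp of an own TSS, an alternative chosen after the data were seen, the share was 10.8 times that of all other protein-coding genes, with no matching on length.

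Chemosensory receptor genes, the Or, Gr and Ir families of odorant, gustatory and ionotropic receptors, held summits less often than length-matched genes. Of 179 genes, 18 had a summit in the window (10.1%), against 69.1 in random lists (95% range 57 to 82), a ratio of 0.260 (adjusted permutation p = 1.3e-04). The strongest were near Or85f (1210), Ir68b (941), Gr89a (838) and Or88a (701). Those of Or85f, Ir68b and Or88a lay in promoters of the neighbouring genes CG8132, yps and CG12402, and that of Gr89a was intergenic. Gr10a, Gr10b and Gr21a had none. Receptor genes that lie side by side, such as Gr10a and Gr10b, have overlapping windows and are not independent in this test. The ratio was 0.0888 for summits within 1 kb of a TSS of the gene, 0.143 among the 1000 strongest peaks and 0.508 with 10 kb either side, and each passed the test. Within 100 bp of an own TSS no receptor gene had a summit, against 7.26% of all other protein-coding genes, not matched on length (exact Fisher test, adjusted p = 2.8e-05).

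The DIP and dpr families, immunoglobulin proteins of the neuronal surface that pair across synapses, also held summits less often. A summit lay in the window of 6 of 30 genes, against 19.1 in random lists (95% range 14 to 24), a ratio of 0.314 (two-sided permutation p = 2.0e-05, the smallest possible, adjusted permutation p = 1.3e-04). Members with summits were led by DIP-alpha (X, 3546121 to 3546515, signal value 1710), dpr14 (1130), dpr19 (746) and dpr20 (536). The DIP-alpha summit was classed as promoter, but the nearest protein-coding TSS was that of ppk8, at 11478 bp. The dpr14 and dpr19 summits were nearest to the TSS of a neighbouring gene, spidey at 226 bp and CG33303 at 144 bp. They also lay within 500 bp of the 5′ ends of dpr14 and dpr19 themselves. DIP-beta, DIP-delta and DIP-epsilon were among those with none. The ratio was 0.323 among the 1000 strongest peaks, which did not pass the test, and 0.197 on the autosome arms alone, which did. Within 100 bp of an own TSS no member had a summit, against 7.18% of all other protein-coding genes, not matched on length. That difference did not pass the exact Fisher test.

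The other 17 lists did not pass the test, and the lists closest to the known role of bsh were among them. That role is in neurons of the optic lobe, whereas the summits come from whole embryos of 10 to 12 h. The lamina and medulla lists are also small, and the power for lists of their size was not simulated. The test therefore cannot decide whether Bsh binds these genes in the optic lobe. Of 15 lamina neuron regulators, bsh itself included, 9 had a summit, against 9.00 in random lists (ratio 1.00, adjusted permutation p = 1). The strongest were intronic at zfh1 (1638), a zinc finger homeodomain factor, and sim (1358), the midline regulator, followed by slp1 (614) and dac (440), while ap, DIP-beta and eya had none. Of 14 medulla regulators, bsh again included, 9 had a summit (ratio 1.16, adjusted permutation p = 0.895). They were led by hth (1266), slp1, D (517) and slp2 (418), and hbn, opa and run had none. In both lists bsh counts only through its summits in the promoter of fbp. Neuronal homeodomain factors had summits at 19 of 34 genes against 20.9 (ratio 0.909, adjusted permutation p = 0.895). These included otp (1584), whose peak was 1 of the 14 in coding exons, tup (1462, 116 bp from the TSS of CG10602), Awh (937) and Lim1 (801). In that list ap, B-H1 and B-H2 had none. Hox genes and cofactors had summits at 6 of 11 genes (ratio 0.843, adjusted permutation p = 0.895), with introns of Antp (919), Abd-B (838) and lab (516) after hth, and none at abd-A, Dfd and exd.

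Among other regulators of the nervous system, temporal factors of embryonic neuroblasts had summits at 3 of 9 genes, grh (1642), dan (253) and pdm2 (163), with none at cas, danr and hb (ratio 0.586, adjusted permutation p = 0.580; without replicate 1 the ratio was 0.381). Proneural and neuroblast genes had them at 7 of 20 (ratio 0.801, adjusted permutation p = 0.895), led by brat (2377), which encodes a brake on neuroblast self-renewal, Dr (606), insc (592) and nerfin-1 (540), and ac, amos and ase had none. The Notch pathway came nearest to the threshold among lists above random, with 12 of 17 genes against 7.97 (ratio 1.51, unadjusted permutation p = 0.0635, adjusted permutation p = 0.318). Its strongest peaks lay near the Enhancer of split genes E(spl)m8-HLH (2046, in the promoter of gro, the corepressor groucho), E(spl)mdelta-HLH (1799) and E(spl)m7-HLH (1713) and in an intron of N (1683). E(spl)m5-HLH, E(spl)mgamma-HLH and H had none. Among the 1000 strongest IDR peaks this list passed the test, with 8 genes against 2.12, a ratio of 3.77. Windows of neighbouring Enhancer of split genes overlap, as those of E(spl)m7-HLH and E(spl)m8-HLH do, though this pair shares no IDR summit. Whether others of the 8 genes share one was not examined. Genes that lie side by side are not independent in this test, so the permutation p may be too small. Axon guidance and adhesion genes had summits at 25 of 32 genes (ratio 1.21, adjusted permutation p = 0.50), led by beat-Ib (2364), Toll-7 (1880), fra (1730) and Sema1a (1676), and beat-Ia, Dscam2 and PlexB had none. Neuronal function genes had them at 11 of 20 (ratio 0.899, adjusted permutation p = 0.895), with a strong peak 257 bp from the TSS of elav (2620), the pan-neuronal RNA-binding protein, then ChAT and VAChT, which share a peak (965), and fne (478), and none at brp, cac and futsch. Glial genes had them at 8 of 14 (ratio 1.07, adjusted permutation p = 1), led by pnt (1481), moody (1480), nrv2 (946) and Gli (615), and alrm, drpr and Eaat1 had none.

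Lists for other tissues and for early patterning likewise did not pass. Mesoderm and muscle genes had summits at 16 of 23 genes (ratio 1.21, adjusted permutation p = 0.658), with the strongest near Mef2 (3511, 170 bp from the TSS of Pdrg1), the muscle differentiation factor, then kirre, sls (1756) and tin (1571), and none at Act57B, bap and Mhc. Trachea and epidermis genes had 13 of 16 (ratio 1.32, adjusted permutation p = 0.50), led by shn (2010), grh, trh (1352) and ct (1092), and btl, kni and m had none. Signalling ligands had 13 of 19 (ratio 1.21, adjusted permutation p = 0.751), led by gbb (2544, 102 bp from the TSS of eIF6), spi (1195), dpp (1109) and vn (981), and hh, scw and upd1 had none. Gut and fat body genes had 7 of 14 (ratio 0.982, adjusted permutation p = 1), led by Lsp2 (1273, 135 bp from the TSS of DEF8), fkh (549), srp (541) and cad (436), and byn, dve and Fbp1 had none. Germline genes had 7 of 17 (ratio 0.882, adjusted permutation p = 0.980), led by ovo (884), piwi (795), twe (767, 120 bp from the TSS of EndoGI) and bgcn (703), and aly, aub and bam had none. Head gap and eye genes had 6 of 15 (ratio 0.678, adjusted permutation p = 0.50), led by sim, dac, eyg (344) and ey (298), and ato, btd and ems had none. Segmentation genes had 7 of 21 (ratio 0.674, adjusted permutation p = 0.50), led by slp1, slp2, wg (356) and inv (322), and en, eve and ftz had none.

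Calls for 4 of these lists appeared with another gene window. For summits within 1 kb of a TSS of the gene, 2 of 34 neuronal homeodomain genes against 13.4 (ratio 0.149) and 1 of 21 segmentation genes against 7.07 (ratio 0.141) passed the test below random. When each summit was given to the gene with the nearest TSS, 15 of 21 segmentation genes against 7.28 (ratio 2.06), 14 of 19 ligands (ratio 1.66) and 14 of 16 trachea and epidermis genes (ratio 1.74) passed above random, so the direction for segmentation genes turned with the window.

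**Figure D3:**
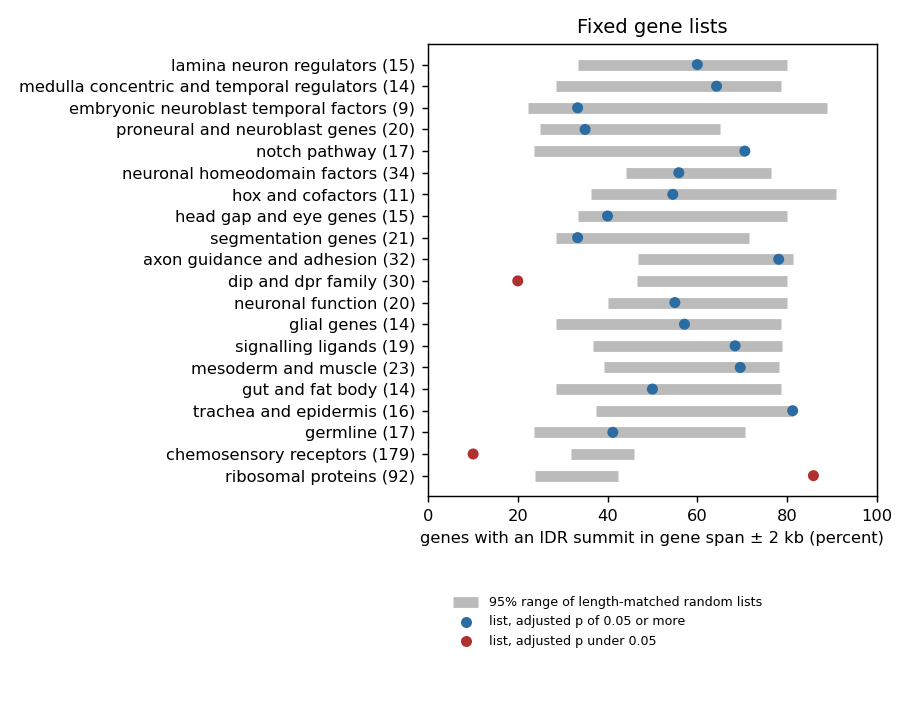
Percent of the genes of each fixed list with an IDR summit in the gene span with 2 kb either side (points; red for an adjusted p under 0.05, blue otherwise), over the 95% range of 100000 length-matched random lists (grey bars); list sizes are in brackets. Ribosomal protein genes lie above the range at 85.9%, and chemosensory receptor genes, at 10.1%, and DIP and dpr genes, at 20%, lie below it.

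Peaks were spread over all major chromosome arms, from 65.2 peaks per Mb on X, 64.2 on 2L and 62.5 on 3L to 55.5 on 3R and 52.2 on 2R. In exact binomial tests against arm length X (1.13-fold, adjusted exact p = 4.5e-07), 2L (1.11-fold, adjusted exact p = 1.1e-05) and 3L (1.09-fold, adjusted exact p = 1.9e-04) were above the mean density. The arm 2R was below it (0.906-fold, adjusted exact p = 9.3e-05), and 3R did not pass (0.963-fold, adjusted exact p = 0.073). The small chromosome 4 held 25 peaks, 18.5 per Mb (0.322-fold, adjusted exact p = 1.7e-11), and Y held none, where 2.67% of peaks would be placed by length; how much of Y can be mapped is unknown. Among the 1000 strongest peaks X (1.12-fold), 3L (1.12-fold) and chromosome 4 (0.510-fold) no longer passed, and 3L did not in the stronger 3963 peaks either (1.05-fold). With Y left out of the arm lengths, a reference chosen after the data were seen, 3R passed below the mean density (0.938-fold).

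Summits were centred on AT-rich sequence. The GC content within 50 bp of the summit was 31.8% ± 9.01 (SD over 7927 peaks), against 43.3% in windows 500 bp away and 42.2% for the arms that hold peaks. The homeodomain core TAATTA occurred in 11% of summit windows and 5.98% of flanks, discordant odds of 1.93 (95% interval 1.71 to 2.17, exact McNemar test, adjusted exact p = 1.2e-28). The variant TAATGA (8.93% against 5.89%, odds 1.58, adjusted exact p = 6.9e-13) and the core TAATTG (10.9% against 9.68%, odds 1.14, adjusted exact p = 0.0137) were also more frequent. The sequences AATTTA (odds 2.46) and ATATAT (odds 2.75), fixed as controls of base composition, had larger odds than any of these cores. The DREF-type site TATCGATA, known from promoters of broadly expressed genes, occurred in 0.946% of summit windows and 0.202% of flanks (odds 4.69, 2.71 to 8.62, adjusted exact p = 6.2e-10), and GATAAG, the GATA type, in 5.75% and 4.78% (odds 1.21, adjusted exact p = 0.00890). Less frequent at summits than in flanks were the E-boxes CACGTG (odds 0.443) and CAGCTG (0.530), the Zelda-type CAGGTA (0.588), the GAGA-type GAGAGA (0.644) and the NK-2-type CAAGTG (0.703). The bicoid-type TAATCC (odds 0.971, adjusted exact p = 0.784) and the Sox-type ACAATG (odds 1.05, adjusted exact p = 0.544) did not pass.

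Against random positions matched on chromosome, GC content and distance class to a TSS, the homeodomain cores were no longer more frequent at summits. The match was on the class and not on the exact distance to the TSS or the side of it. Differences in promoter peaks are therefore not controlled for position within the promoter. TAATTA had odds of 0.924 (0.835 to 1.02), TAATGA 0.971, and TAATTG was less frequent at summits (odds 0.832). Sites that remained more frequent in that comparison were TATCGATA (odds 2.34, 1.53 to 3.66), GATAAG (1.32) and ATATAT (1.16), and none of the 5 motifs rarer than in flanks passed over all peaks. The excess of TATCGATA lay in promoter peaks, at 2.31% of summits against 1.08% of matched positions (odds 2.13), whereas in other peaks the odds were 0.409 and did not pass; the difference between these classes was not tested. Outside promoters CAAGTG (odds 1.33), GATAAG (1.38) and ATATAT (1.19) were more frequent than at matched positions, and TAATTG (0.806) and AATTTA (0.870) less. In promoter peaks ATATAT (1.27) was more frequent, and TAATTG (0.801) and ACAATG (0.701) less. Calls against flanks were lost for TATCGATA among the 3963 stronger peaks (odds 1.80) and the 1000 strongest (1.5), for GATAAG (1.20 and 0.875) and CAGGTA (0.863 and 0.542) in the same sets, and for TAATTG without replicate 1 (1.07) or within 100 bp of the summit (1.08). GATAAG also lost its call within 25 bp of the summit (1.17) and with flanks 1000 bp away (1.1), and GAGAGA lost its call and turned within 100 bp of the summit (1.045).

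**Figure D4:**
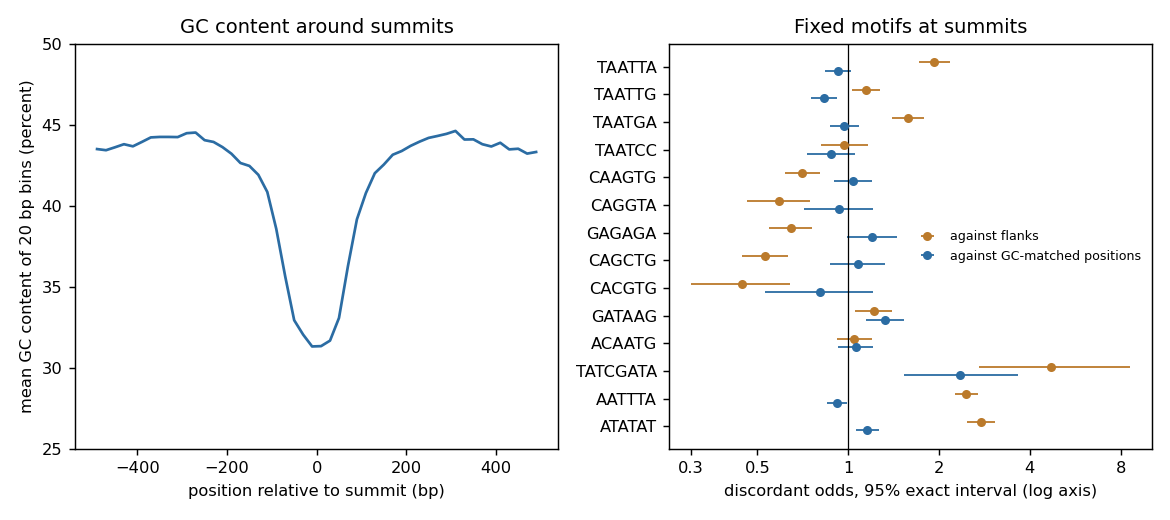
Left, mean GC content in 20 bp bins up to 500 bp either side of the 7927 IDR summits, falling to 31.3% beside the summit. Right, discordant odds with exact 95% intervals (log axis) of each fixed motif within 50 bp of the summit, against flanks (orange) and against positions matched on GC content and TSS class (blue); TAATTA lies at 1.93 against flanks and 0.924 against matched positions.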

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

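The alternatives with lists matched on TSS count, with summits within 100 bp of an own TSS, with locations at GC-matched positions and with arm lengths without Y were chosen after the data were seen. Of 549 values for single classes, arms, lists and motifs under alternatives, 464 kept their direction and their side of the threshold, 23 lost a call, 6 gained one and 56 changed direction. Of 75 values for whole comparisons, 66 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times; among these the replicate overlap ran from 56.3% to 90.7%. The promoter excess held in all alternatives run, from 1.97-fold to 3.69-fold, and so did the depletion of coding exons and 3′ UTRs and the low ratio of chemosensory receptor genes. The strongest peaks of the pooled list are the IDR peaks themselves, so that alternative tests nothing except another random draw. The cause of the changes below was not tested, except that smaller sets hold fewer peaks. No paired analysis was possible because there is only 1 group.

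For the whole comparisons, matching by summits within 100 bp gave 97.54% of IDR peaks in both replicates and a rho of 0.894, and the stronger 3963 peaks gave 99.6% and 0.915. The 1000 strongest peaks gave 3 arms past the threshold. Gene lists past it numbered 5 within 1 kb of a TSS and 6 by nearest TSS. Against positions matched on GC content and TSS class, 3 motifs were more frequent at summits and 1 less frequent.

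Most changes of direction were between values that did not pass in either setting. Ratios among the stronger 3963 peaks were 1.15 for germline, 1.23 for gut and fat body, 0.914 for medulla and 1.02 for proneural lists, and TAATCC had odds of 1.13. Among the 1000 strongest peaks they were 0.745 for lamina and 0.477 for medulla lists, with a fold of 0.936 for introns and odds of 0.875 for GATAAG and 1.32 for TAATCC. In peaks of replicate 1 overlapping replicate 2 they were 1.1 for germline and 0.948 for lamina lists, and 0.957 for ACAATG. With 1 replicate left out, the germline ratio ran from 0.9999 to 1 and the lamina ratio from 0.990 to 0.998.

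By nearest TSS the ratios were 1.24 for neuroblast temporal, 1.33 for germline, 1.36 for gut and fat body, 1.44 for head and eye, 1.49 for Hox, 0.962 for lamina, 1.23 for homeodomain, 1.47 for proneural and 2.06 for segmentation lists. Of these, segmentation passed the test. With 10 kb either side they were 1.09 for germline, 1.00 for head and eye (1.005), 1.14 for Hox and 0.929 for lamina lists. Within 1 kb of a TSS they were 0.353 for lamina, 0.394 for medulla and 0.561 for ligand lists. Within 100 bp of an own TSS the ratios were taken to the share of all other protein-coding genes, with no matching on length. There they were 0.997 for glial and for medulla, 0 for lamina, 0.607 for mesoderm, 1.40 for proneural and 0.734 for ligand lists. Against random lists matched on length and TSS count the ratios were 1.26 for gut and fat body, 1.20 for homeodomain and 1.09 for proneural lists. On autosome arms alone the neuronal function ratio was 1.02.

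Against positions matched on GC content and TSS class the odds were 0.917 for AATTTA, 1.03 for CAAGTG (1.035), 1.07 for CAGCTG, 1.20 for GAGAGA, 0.971 for TAATGA, 0.924 for TAATTA and 0.832 for TAATTG, which passed in the new direction. ACAATG had odds of 0.989 in merged peaks, 0.960 with flanks 1000 bp away and 0.976 within 100 bp of the summit, where GAGAGA had 1.04 (1.045). Introns had a fold of 0.990 with promoters of 1000 bp (0.9905) and 0.940 against GC-matched positions, which passed in the new direction and where 5′ UTRs had 1.1. Sequencing depth is unknown, so how many weak sites the lists miss cannot be stated.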

Other observations

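The tests with lists matched on TSS count, with summits within 100 bp of an own TSS, with locations at GC-matched positions, with summits counted for 1 gene alone and of 8-mers were chosen only after the results they bear on were seen, and TAATTA at matched positions, a comparison fixed beforehand, was taken as a test of AT-rich sequence only after its odds were known. The side of the TSS, divergent promoters and gene types were not among the tests fixed beforehand either. Summits near protein-coding genes lay mostly upstream. Of 2639 summits within 500 bp of a protein-coding TSS, 2123 were on the upstream side, and the median position was −116 bp, with quartiles at −206 and −32 bp. Divergent promoters, with a TSS on the opposite strand within 1 kb upstream, held a summit in 37.1% of 4650 cases, against 12.8% of other protein-coding promoters, and in 20.02% against 12.1% with each summit counted for the nearest gene alone. By gene type, a summit lay within 500 bp of 2912 of 13945 protein-coding genes (20.9%; mean of shifted summits 5.67%) and of 310 of 3261 non-coding RNA genes (9.51%; 5.70%). Of snoRNA genes 7.81% (permutation p = 0.180, adjusted p = 0.225) and of pseudogenes 3.73% (permutation p and adjusted p = 0.934) had one, inside the range of the shifts.

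Among the 2080 distinct 6-mers, 107 were more frequent at summits both than in flanks and than at positions matched on GC content and TSS class. The one with the smallest p against matched positions was ACACTG, in 5.31% of summit windows, 3.71% of flanks and 2.86% of matched positions (odds 1.92, exact McNemar test, adjusted p = 8.4e-12), followed by ACAGTG with 5.08%, 4.08% and 2.76%. By odds ACACTG did not lead, since CGCTAG had 2.11. These were picked after their values were seen.

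Ribosomal protein genes held summits more often, and chemosensory receptor genes less often, than genes with windows of the same length. Against random lists matched also on the number of TSS positions the ratios were 2.02 and 0.337, both outside the 95% range of the lists, which argues against gene-dense or gene-poor neighbourhoods as the whole cause. Summits of neighbouring genes do not account for the ribosomal protein genes either, since 72.8% of them had a summit within 100 bp of an own TSS, against 6.73% of other genes (exact Fisher test, adjusted p = 1.9e-55). Open is whether abundant transcription at these genes draws DNA into the precipitate, since no expression data or untagged control were analysed. With 1 group, no biological explanation was tested for this or the patterns that follow.

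Summits avoided coding exons and were richer in TAATTA than their flanks, and AT-rich summit sequence is a candidate explanation of both. Of random positions matched on GC content, 3.31% lay in coding exons (2.92 to 3.72), well under the 13.1% of all bases but far above the 0.177% of summits, so base composition may account for part of the depletion and not for all of it. The odds of TAATTA fell from 1.93 (1.71 to 2.17) against flanks to 0.924 (0.835 to 1.02) against matched positions, so the excess over flanks may come from base composition alone. A binding preference of Bsh for this core is neither shown nor excluded by that comparison, since AT-rich positions hold the core often by themselves.

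The promoter excess and its concentration at divergent promoters were weighed against gene density, against summits between paired TSSs counted for both genes, and against highly transcribed short RNA genes drawn into the precipitate. Within strata of equal TSS number within 5 kb, bound promoters were divergent more often than unbound ones, with a Mantel-Haenszel odds ratio of 3.96, which fell to 1.87 (95% bootstrap interval over 1 Mb blocks 1.69 to 2.08) with each summit counted for the nearest gene alone. Double counting may thus account for part of the excess at divergent promoters, and the remainder, above the highest of 1000 circular shifts (0.916), argues against it and gene density as the whole cause. Of 290 tRNA genes, 36 (12.4%) had a summit within 500 bp, above the highest of 1000 circular shifts (11.7%, permutation p = 1.0e-03, the smallest possible, adjusted p = 0.00167), which is what the last explanation predicts. Protein-coding genes (20.9%, highest shift 6.69%) and non-coding RNA genes (9.51%, highest shift 7.76%) exceeded every shift too. The test therefore does not single out tRNA genes, and whether such loci add to the set stays open. With 36 tRNA genes beside 2912 protein-coding ones they cannot make up most promoter summits, and whether highly transcribed protein-coding genes behave alike stays open.

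A last hypothesis, with no such protein tested, is that some summits mark sites of insulator or core promoter factors rather than a homeodomain site. The 10 most enriched 8-mers at summits on chromosome 2 were tested on 5072 summits of chromosomes 3 and X against matched positions, and 6 of the 10 passed the exact McNemar test, all of them more frequent at summits, which argues against chance among many 8-mers for these 6 as a set, though they are not 6 separate sequences: GATGGCGC, AGATGGCG and ATGGCGCC are shifted copies of 1 sequence and AGGTGGCG and GCGCCACC of another. Leading by odds were GATGGCGC, in 0.670% of summits against 0.0591% (odds 16.5, 4.22 to 142) and 0.296% of flanks, AGGTGGCG (odds 7) and GCGCCACC (odds 7.33), which resemble the known core of the insulator protein CTCF, whereas GGGTAAAC (odds 3.6, adjusted exact p = 0.0212) passed and does not resemble it. AGATGGCG (odds 4.4) occurred in the most summits of the 10, 0.87%. The 4 that did not pass stay open. TCTCACAA had odds of 2.2 (0.705 to 8.08) and CTGAGAGA 1.92 (0.915 to 4.23). GGTCACAC, which resembles the core promoter element Motif 1, had 1.5 (0.728 to 3.19), and CTGTGAAG had 1. The bound first set to exclude chance asked for odds above 1 for all 10 and was narrowed to those that pass after the result was seen.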
